A study of Oryza sativa with 2 samples.

How the data were processed

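Degradome sequencing reads the 5' ends of RNA fragments that have lost their cap, so that a transcript cut at 1 place by a small RNA gives a pile of reads that start there. The series holds 2 such libraries from mesocotyls of the indica rice cultivar P25, 1 from seedlings grown for 5 days in the dark (D_5d, the dark library) and 1 from seedlings given 1 h of light after 5 days in the dark (L_1h, the light library). The libraries were sequenced on a HiSeq instrument from total RNA, per the labels' protocols. The aligner, the target finder, the genome build and the annotation are not given in the sources used here.

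The deposited table pairs small RNAs with transcripts and gives, for each pair and library, 5 kinds of value, per the file headers. Raw read counts are whole numbers of reads that start at the cleavage position, as the authors deposited them, with a blank where a library has none. The authors' normalized reads are a signal in which raw reads are divided by a number of matching places that lies between 1 and 10, as the deposited values show. TPB, reads relative to the library total times a fixed number, is a signal that the authors made from the normalized reads, and the deposited values are the normalized reads times 1 constant per library. The inverse of that constant is a whole number of reads in each library, which was taken as the library total. Whether this counts all reads or mapped reads is not given in the sources used here. The authors also deposited a p-value for each pair in each library, p-values between the libraries, and a degradome category. The alignment score is a mispairing penalty, per the file headers, and runs from 0 to 4 in the deposited table. The authors' deposited log2 fold change is dark over light, which the values show, so its sign is the opposite of the light over dark ratios given here.

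Some deposited columns name a dark library of 1 h where the labels name 5 days. They were read as the dark library, since the TPB column headed D_5d is those normalized reads times 1 constant. A further 20 columns of values per sample, in the study's auxin and cell wall sheets, were not used, and these sheets served only for which sites they list. In the first sheet 1 line was empty and gave no value. Gene identifiers are those of the deposited table and were not matched to a genome here, so a site is given as a position on its transcript. Symbols and descriptions are those the deposited table pairs with the transcripts, and several look borrowed from other species or disagree with each other.

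Pairs were collapsed to sites, a site being 1 transcript and 1 cleavage position, with the lowest category and the lowest p-value among its pairs. By common usage category 0 marks the single highest position of a transcript, and in the deposited values category 4 held the positions with 1 read. Genes were formed from all transcript versions, with TPB summed over versions and positions and raw reads summed over the positions of the version with most. The read total was 15422946 in the dark library and 34051452 in the light library, so 1 unshared read is worth 64.8 and 29.4 TPB. A floor of 3 reads, per library, stands at 195 and 88.1 TPB. A ratio against a library with no read is given as a fold against that floor. It leaves out the counting error of the library that has reads, so the counting interval can reach nearer to 1.

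The abundance of a site or gene was compared as light over dark TPB. Its 95% interval is an exact Clopper-Pearson interval of the raw reads, scaled by the library totals and then, where both libraries have reads, to the TPB ratio. For most genes this is the ratio of raw reads or close to it, and with raw reads alone 2 of the called genes, REFA1 and ZS11g0552900, were not called. A site or gene was called higher or lower when the ratio was at least 2-fold and the interval excluded 1. With 1 library per condition there is no replicate check and no test between the conditions was made. The intervals compare the libraries, not the conditions. They cover counting error only, since PCR reads without molecular identifiers are not independent molecules. Shares of sites have Wilson 95% intervals, which take sites as independent and are too narrow, since transcript versions can share reads.

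Lists of genes were fixed before the data were examined. They comprise 21 lists by small RNA family and target class, namely SPL, GAMYB and TCP, ARF by miR160, ARF by miR167, TAS3, TIR1/AFB, NAC, HD-ZIP III, AGO1, DCL1, NF-YA, GRAS, AP2, F-box by miR394, sulfate, GRF, copper proteins, superoxide dismutase, phosphate, MADS, and any target of miR2118, miR1432 or miR530. A further 17 lists rest on words in the deposited descriptions, namely chlorophyll and photosystem, light signalling, auxin, gibberellin, brassinosteroid, ethylene, cytokinin, abscisic acid, jasmonate, cell wall, ribosomal protein and translation, histone, heat shock, ubiquitin and F-box, protein kinase, transporter, and transposon. The text patterns that recognise each class were written after the descriptions were seen. For each list the median log2 ratio, with a pseudocount of 0.5 read in each library, was placed among 10000 random lists of the same size drawn from 10 bins of mean abundance. The percentile describes these libraries and is no test.

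The rule for named sites was also fixed before the data were examined. It takes the 10 sites with the most normalized reads in each library, the 10 largest and the 10 smallest ratios among sites with at least 20 raw reads in all and a category of 0 to 2 in a library, the 2 sites with the most reads of each small RNA list, and the 10 sites with the most reads of each study sheet. Called genes named outside this rule were chosen after their values were seen, and the text says so. Of the sites the rule names, 1 is not reported here.

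The alternatives were items collapsed to genes, categories 0 to 2, category 0 alone, the authors' p-value of 0.05 or lower, a score of 4 or lower, at least 10 reads, size factors from the median ratio or from the sum over sites present in both libraries, a minimum of 1.5-fold or 4-fold, and a pseudocount of 1 read. Added after seeing the data were thinning of the light library, the floor in place of 0 reads, raw reads in place of TPB for sites and for genes, the same TPB pseudocount in both libraries, the sum size factor for lists, and leaving out the pairs of a pair of simple-repeat small RNAs.

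The calls were tested on simulated data, with reads drawn for 995 sites in each of 20 runs and 200 sites changed. On average 4.5 unchanged sites were called per run. The simulated sites had independent counts and no versions that share reads, unlike the real sites. The figures of these runs therefore do not carry over to the real calls. Of sites with 20 or more reads, 87.2% of those simulated 4-fold higher and 34.7% of those 2-fold higher were called, against 12.1% and 5.16% of all sites. For lowered sites with 20 or more reads the shares were 96.4% at a fold of 0.25 and 50.5% at a fold of 0.5. For the lists, 200 simulated lists of 20 sites gave 7.5% of unchanged lists outside the central 95% and 100% of 2-fold higher lists above it. These lists were drawn only from sites with 20 or more expected reads, with independent counts and without versions that share reads. Many sites of the real lists have fewer reads or share them, so these shares do not carry over to them. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.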

Results

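The mesocotyl is the stem-like organ that lifts the shoot of a grass seedling through the soil, and it elongates in the dark and stops in light. Cleaved transcripts were profiled by degradome sequencing in mesocotyls after 5 days of darkness and in mesocotyls given 1 h of light after the same 5 days, with 1 library each. The library totals inferred from TPB were 15422946 reads in the dark library and 34051452 in the light library, a ratio of 2.21, and whether they count all or only mapped reads is not given in the sources used here. Of these totals 0.0356% and 0.0490% of reads started at a listed cleavage site, and the median site had 2 raw reads in either library. Of 25653 listed pairs of a small RNA and a transcript, 3262 (12.7%) had reads, on 2064 sites of 1730 transcripts from 823 genes. The cut lay opposite base 10 of the small RNA in 2999 of these pairs, base 9 in 103 and base 11 in 160. No pair with reads lay elsewhere, so the listing may have required these bases and the count is no test of cleavage.

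The first comparison asked which transcripts were cut in the dark and which after light. Transcripts of the auxin response factors ARF22, ARF18, ARF8 and ARF10, which miR160 targets, gave many of the most abundant fragments in either library, together with 1 unnamed miR528 target. ARF22, cut at position 1367 of its transcript, stood at 36374 TPB in the dark library and 50571 in the light library. The miR528 target, ZS07t0470600-01 cut at position 463, stood at 18479 and 78323 TPB and was the most abundant site of the light library. SPL16, a squamosa promoter-binding protein gene cut by miR156 at position 1864, stood at 9207 and 10719 TPB. These sites were in category 0, the highest position of their transcript, in both libraries.

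The dark library had 1075 sites and the light library 1681, of which 692 (33.5% of all sites) were found in both. Genes with a site numbered 413 and 665. Among the 383 sites of the dark library alone 279 had 1 read, and none had more than 7. Among the 989 sites of the light library alone 475 had 1 read, and none had more than 20. Thinning the light library to the read total of the dark library, a step added after the data were seen, left 1211 expected sites. The computed SD of 16 takes sites as independent and is too small, since transcript versions share reads. Over genes, 478 were expected against 413 in the dark library, with an SD of the difference of 12.4.

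Clear cuts belonged mostly to known small RNA targets. Category 0 was reached by 139 sites of 63 genes in at least 1 library, and 103 of these sites (74.1%), from 44 genes, were in the target-class lists. ARF, SPL, NF-YA, HD-ZIP III and GRF genes were among them. Category 0 took 95 of 1075 sites in the dark library (8.84%, 95% interval 7.28 to 10.7) and 114 of 1681 in the light library (6.78%, 5.68 to 8.08), intervals that overlap. These sites came from 49 and 55 genes. The intervals take transcript versions that share reads as separate sites, so they are too narrow. Category 0 held 72.2% and 79.0% of the TPB at sites. Category 2 was less frequent in the dark library, at 45.1% against 52.5%, and category 4, with 1 read per site, was more frequent, at 43.7% against 35.8%. Category 4 depends on depth by its definition. Of the 95 category 0 sites of the dark library 93 also had reads in the light library, and of the 114 of the light library 101 had reads in the dark library.

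**Figure D1:**
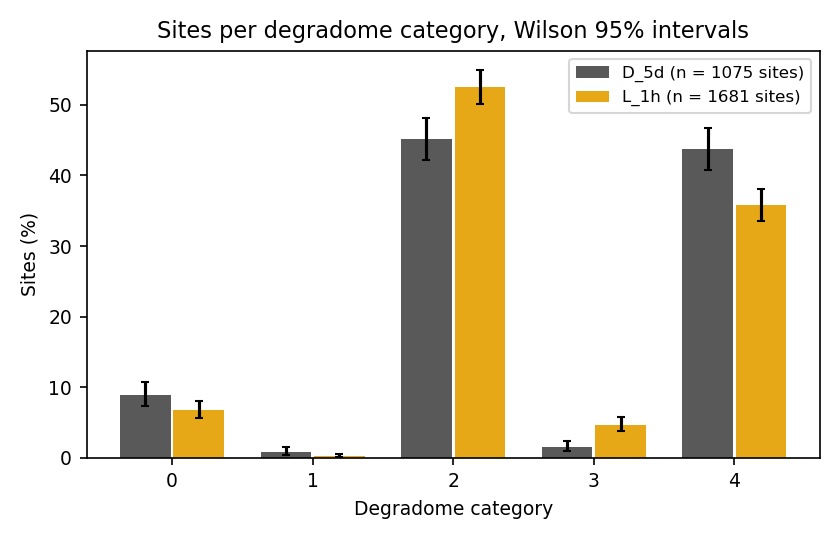
Share of sites (%) in degradome categories 0 to 4 in the dark (1075 sites) and light (1681 sites) libraries, with Wilson 95% intervals as error bars. The intervals take sites as independent and are too narrow, since transcript versions share reads. Category 2 is the largest class in the light library at 52.5%, and category 0 holds 8.84% and 6.78% of sites.

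The second comparison set the abundance of each cut in the light library against the dark library. Ratios are light over dark, the opposite direction of the log2 fold change in the authors' deposited table, and with 1 library per condition they have no replicate check. Fragments of ARF10, of an AP2 gene, of GRF5 and of NAC021 were at least 2-fold more abundant in the light library, as were those of the unnamed miR528 target, of HMG3 and of PSK5. Fragments of SPL19 and of another NAC021 copy were less abundant. No HD-ZIP III or NF-YA gene was called. In all, 27 genes were called higher in the light library and 19 lower, of which 10 and 3 belonged to the target-class lists. With the sum scaling the target-class calls were 3 higher and 7 lower, and 3 and 2 were called under all 3 scalings, so the balance between them depends on the scaling.

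At the level of sites 52 were called higher and 49 lower, so 51.5% of calls were higher. This share was 63.9% with the median ratio over shared sites as the size factor and 17.2% with the sum over shared sites. The median shared site stood at a log2 ratio of -0.18 on the authors' scale, and the sum over shared sites at 0.44. Of the called genes, 12 of those higher and 17 of those lower were called under all 3 scalings. No read was seen in the dark library for 24 of the 52 higher sites, nor in the light library for 18 of the 49 lower ones, and only 3 of each were at least 2-fold against the floor of 3 reads. Most calls of lower genes rested on few reads, 15 of 19 having 20 or fewer in all.

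**Figure D2:**
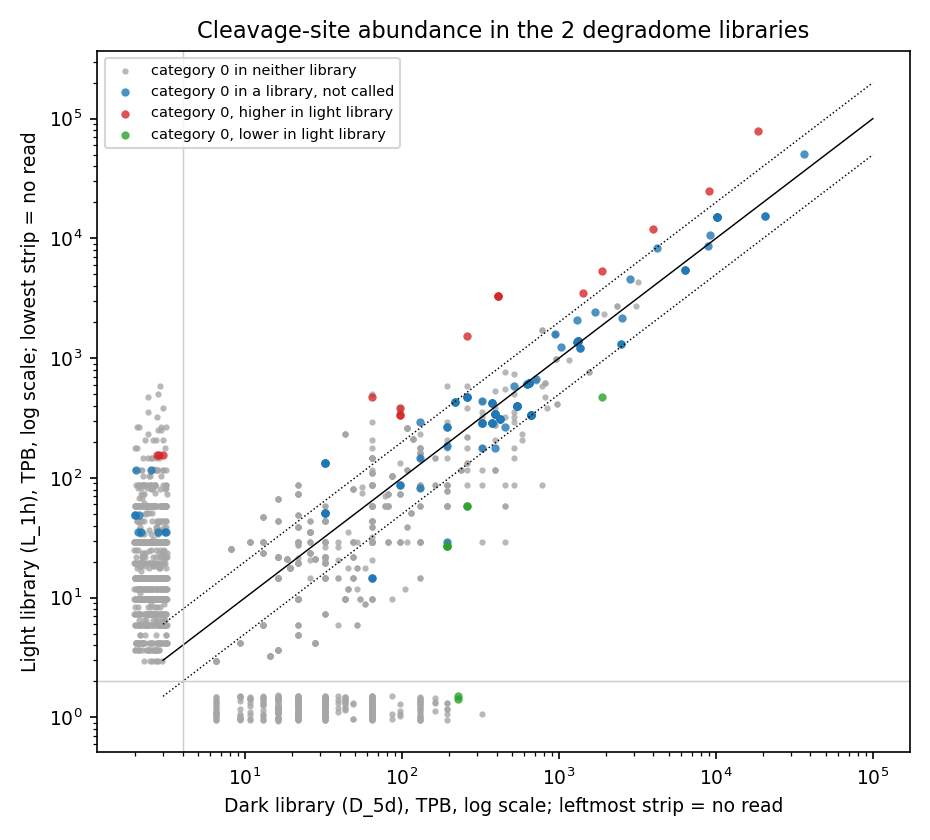
TPB of each of the 2064 sites in the dark library (horizontal) and the light library (vertical), both on log scales, with sites without a read in the outer strips, the solid line at equality and dotted lines at 2-fold. Colours mark category 0 and the calls (52 sites higher and 49 lower over all categories), and the most abundant sites lie near the line of equality or above it.

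Among the miR160 targets, 1 of 5 ARF genes was called higher and none lower. ARF10 fragments were 2.66 times as abundant in the light library (95% counting interval 2.23 to 3.19), a call that was lost at 1.96 with the sum scaling. ARF18 stood at 1.48 (1.36 to 1.60) and ARF22 at 1.39 (1.27 to 1.53), both above 1 but under 2-fold, and with the sum scaling at 1.09 and 1.03. ARF8 was on the other side of 1, at 0.759 (0.688 to 0.839), under all 3 scalings. ARF13 had 3 and 6 reads. The miR167 targets ARF12 and ARF25 were not called, with 10 against 14 and 3 against 5 reads. The auxin receptor genes of the TIR1/AFB class, cut by miR393, were not called either, at 0.906 (0.645 to 1.28) for Os04g0395600 and 0.761 (0.524 to 1.12) for Os05g0150500. At site level 4 of their 8 sites were called lower, namely 3 transcript versions of a position of Os04g0395600 with 9 and 6 reads, and position 1980 of Os05g0150500 at 0.283 (0.0729 to 0.981) on 8 and 5 reads. None of the 4 was called with the median scaling.

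Developmental regulators cut by miR172, miR396 and miR164 gave most of the higher calls among target classes. Of 5 AP2 genes 2 were called higher and none lower, led by ZS05g0027300 at 3.02 (2.32 to 3.99), which was called under all 3 scalings. The other, ZS04g0775700, stood at 2.0 (1.06 to 4.11), while ZS03g0765600 at 4.08 (0.976 to 36.2) was not called on 2 and 18 reads. With the median scaling ZS03g0765600 was called higher as well, at 4.62. Of 8 GRF genes, which promote cell proliferation in growing organs, 3 were called higher and none lower. GRF5 stood at 2.47 (1.56 to 4.09) and GRF4 at 3.47 (1.05 to 18.1) on 3 and 23 reads. GRF6, with 0 and 16 reads, was 2.42-fold higher against the floor, with a counting interval of the ratio from 1.75. GRF3, GRF10, GRF8 and GRF1 were not called, and the median GRF ratio of 1.15 turned to 0.854 with the sum scaling. Of 5 NAC genes, whose class includes regulators of organ boundaries, 2 were called higher and 1 lower. The NAC021 copy ZS12g0491700 stood at 2.60 (1.78 to 3.92) and NAC100 at 2.13 (1.38 to 3.38), whereas NAC021 ZS08g0123100 stood at 0.373 (0.170 to 0.804). With the sum scaling GRF5, GRF4, NAC021 ZS12g0491700, NAC100 and AP2 ZS04g0775700 were no longer called. GRF4, GRF6, NAC100, AP2 ZS04g0775700 and the 2 called SCL6 genes were named after their values were seen.

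The GRAS genes cut by miR171 went both ways, with 1 of 4 called higher and 1 lower. SCL6 ZS02g0545600 stood at 6.49 (2.08 to 32.7) on 3 and 43 reads, under all 3 scalings, and SCL6 ZS02g0545800 at 0.371 (0.136 to 0.984), a call lost with the median scaling. The more deeply read copies stood at 1.75 (1.39 to 2.22) for ZS04g0662300 and 0.522 (0.408 to 0.668) for ZS06g0014000, with intervals on either side of 1. With the sum scaling ZS06g0014000 was called lower, at 0.385. Of 8 SPL genes, which time growth phases under miR156, 1 was called lower and none higher. SPL19 stood at 0.262 (0.148 to 0.455) under the authors' scaling and was lower under all 3. With the sum scaling SPL4 and SPL12 were called lower as well, and with the median scaling SPL17 was called higher, at 4.36. SPL12 stood at 0.618 (0.483 to 0.794) on 115 and 157 reads, below 1 but under 2-fold, and these 3 genes were named after their values were seen. At site level 9 of 60 SPL sites were called lower and none higher, 8 of them transcript versions of 1 position each of SPL4 and SPL12 with 12 reads or fewer. SPL16 was at 1.24 (1.05 to 1.46) and, with the sum scaling, on the other side of 1 at 0.912.

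**Figure D3:**
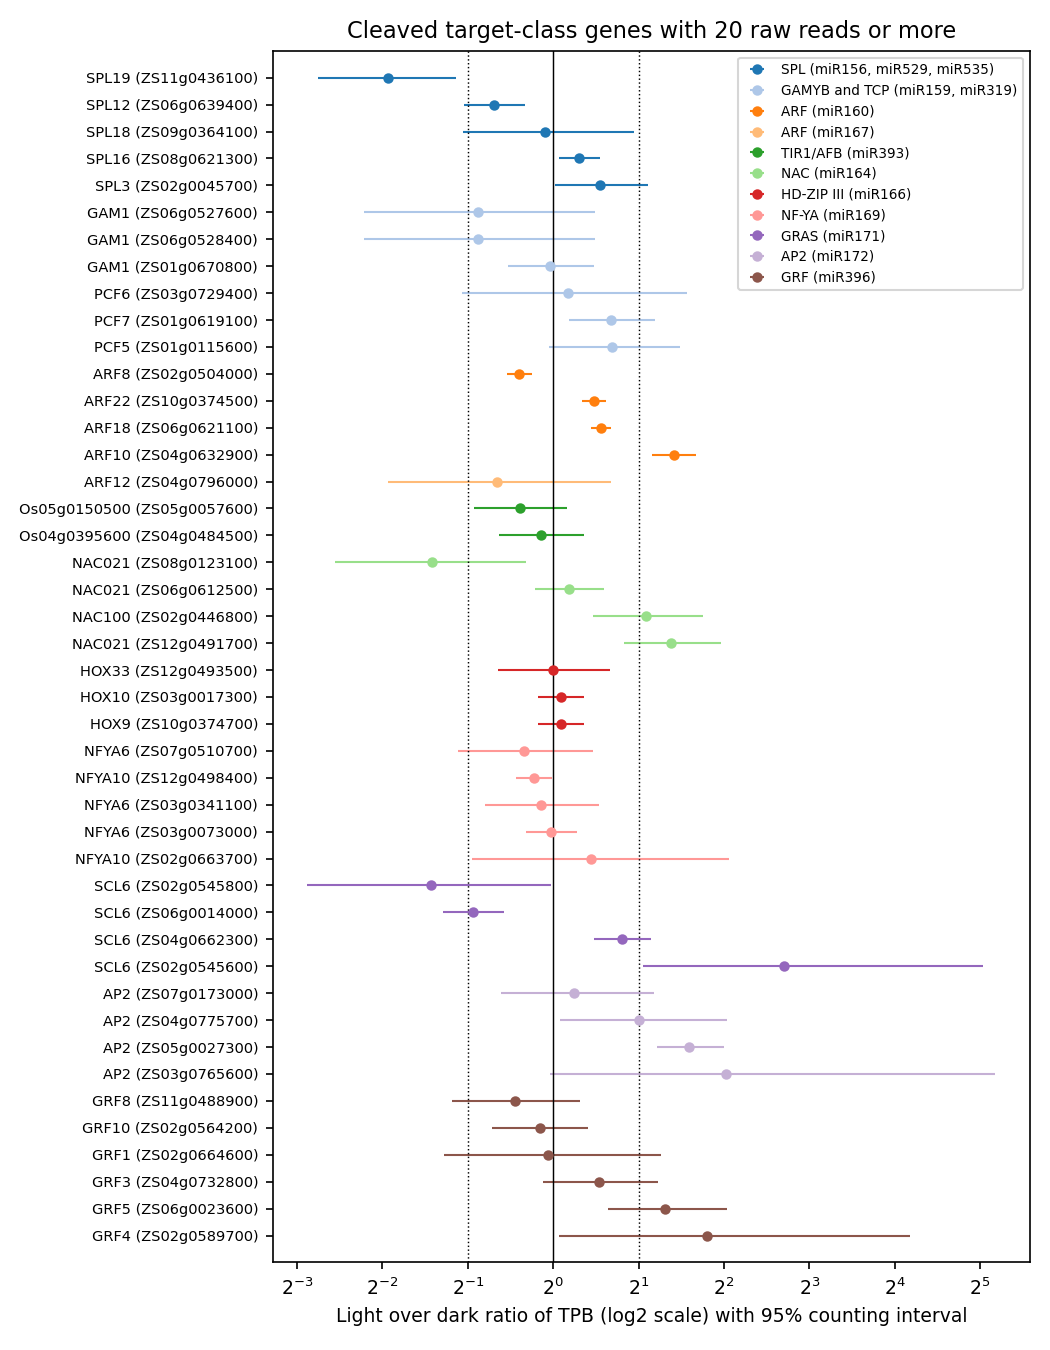
Light over dark ratio of TPB (log2 axis) with 95% counting intervals for target-class genes with at least 20 raw reads and reads in both libraries, coloured by list, with dotted lines at 2-fold. ARF10 (2.66), AP2 ZS05g0027300 (3.02) and SCL6 ZS02g0545600 (6.49) lie beyond the upper line and SPL19 (0.262) beyond the lower one.

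The other target classes had 1 called gene among them, a copper protein gene. The HD-ZIP III genes HOX9 and HOX10, which set leaf and vascular polarity and share most of their reads here, both stood at 1.06, with intervals of 0.884 to 1.29 and 0.882 to 1.29. With the sum scaling they stood at 0.785 and 0.784. HOX33 stood at 0.996 (0.638 to 1.59), and HOX29 had 1 read in either library. Of the 5 NF-YA genes NFYA6 ZS03g0073000 stood at 0.982 (0.799 to 1.21) and NFYA10 ZS12g0498400 at 0.855 (0.741 to 0.988), an interval below 1, and with the sum scaling at 0.724 and 0.630. The 7 GAMYB and TCP genes included PCF7 at 1.60 (1.14 to 2.28) and PCF5 at 1.61 (0.968 to 2.79). AGO1B and DCL1, parts of the small RNA machinery itself, had 6 against 13 and 5 against 6 reads, at 0.981 (0.348 to 3.15) and 0.544 (0.138 to 2.25), and no difference was detectable at this depth. The 2 genes of the phosphate list and the 14 targets of miR2118, miR1432 or miR530 were not called, though with the sum scaling 1 of the 14 targets was called lower. In the phosphate list OsI_17046 had 3 reads in either library, and RBL19 in the miR2118 list stood at 0.906 (0.315 to 2.94). Of 5 copper protein genes 1 was called higher, ZS09g0219100, which resembles L-ascorbate oxidase. With 0 and 11 reads it was 1.66-fold higher against the floor, under 2-fold, with an interval from 1.14. It was not called with the sum scaling, and LAC8 had 0 and 3 reads. The 6 remaining lists (TAS3, F-box by miR394, sulfate, superoxide dismutase, MADS and transposon) had no site.

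Over all 79 target-class genes the median ratio was 0.980, with 38 genes above and 41 below 1, and it was 1.11 with the median scaling and 0.723 with the sum scaling. AP2 and NAC genes had median ratios of 1.94 and 1.90, above 1 under the 3 scalings. Over AP2 sites the median log2 ratio was -0.64, the other sign, with 13 of 26 sites above 0 and 13 below. The 13 below had 1 or 2 dark reads each and none in the light library, and were transcript versions of 2 genes. The copper protein median of 2.72 rests on the pseudocount, since 4 of the 5 genes had no read in the dark library. With such genes at their bound against the floor its median log2 ratio was -1.14, so no direction is given for this class. At gene level no list lay outside the central 95% of random lists, and NAC came nearest to the upper end at a percentile of 94.9. At site level 8 lists did, but transcript versions that share the same reads enter there as separate sites. All target-class sites joined had a median log2 ratio of -0.14, below 0 and yet at a percentile of 99.9, since random lists had -0.29.

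The largest ratios lay partly outside the target-class lists. HMG3 is by its symbols a 3-hydroxy-3-methylglutaryl-CoA reductase, the enzyme that commits carbon to the mevalonate pathway. HMG3 stood at 8.03 (5.06 to 13.5) with 19 and 337 reads at a site paired with miR1861 variants. The alignment score of this site was 4, the highest penalty in the deposited table. The authors' deposited p-values for the site were 0.999999 in the dark library and 0.174 in the light library. Its category was 2 in the dark library and 0 in the light library. Whether miR1861 cut HMG3 is therefore left open. PSK5, a precursor gene of the growth peptide phytosulfokine with a miR164 site, stood at 5.89 (2.17 to 22.4) on 4 and 52 reads. The unnamed miR528 target ZS07t0470600-01, whose deposited description gives only an anchored component of the plasma membrane, stood at 4.24 (3.75 to 4.81) on 285 and 2667 reads. It was left out of the copper protein list, which includes miR528, only because its description lacks the words of that list. HMG3, PSK5 and this target were called under all 3 scalings. At1g28600, described as alpha-L-fucosidase-like, stood at 5.44 (1.35 to 47.4) on 2 and 24 reads at a site of a simple-repeat small RNA, a call lost with the sum scaling.

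The smallest ratios by the same rule were less extreme than the largest. The rule asks for at least 20 raw reads in all, and 15 of the 19 genes called lower had 20 or fewer. Among genes called lower with reads in both libraries, ratios reached 0.0647, a value looked up after the data were seen. The contrast therefore holds only under this rule. SPL19 had the smallest, 0.25 (0.127 to 0.476) at position 1110. An unnamed miR408 site at position 96 of ZS03t0155600-01 and the NAC021 site at position 1043 of ZS08t0123100-01 had the same counts, 15 and 14 reads, and stood at 0.423 (0.189 to 0.939). Reads at other positions of ZS03g0155600 took the gene to 0.627 (0.368 to 1.08), which was not called on the authors' scale but was with the sum scaling, at 0.462. The SCL6 site at position 725 of ZS06t0014000-01 stood at 0.491 (0.325 to 0.742). The miR408, NAC021 and SCL6 sites were not called with the median scaling. MT4C, a metallothionein gene, REFA1, an elongation factor gene, and GLYI-11, a glyoxalase gene, had ratios of 0.453, 0.453 and 0.494 with intervals that include 1. With the sum scaling these sites were called lower, at 0.334, 0.334 and 0.364.

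Among the 16 annotation lists with a gene, 7 had a called gene and 9 had none. The auxin list had 2 of 26 genes higher and 1 lower, namely ARF10 and the NAC021 copies already given. The abscisic acid list had 1 of 16 higher, again ARF10. The chlorophyll and photosystem list had 1 of 13 higher, lhcA-P4, a light-harvesting protein gene by name, at a site of a simple-repeat small RNA. With 0 and 11 reads lhcA-P4 was 1.66-fold higher against the floor, also under 2-fold, with an interval from 1.14. It was not called with the sum scaling. The cell wall list had 1 of 11 higher, NAC043 with 0 and 13 reads, again at a site of a simple-repeat small RNA. The ribosomal list had RPL14A higher at 7.70 on 1 and 17 reads (interval 1.21 to 322) and REFA1 lower at 0.367 (0.141 to 0.963), of 29 genes. The REFA1 call comes from TPB summed over 28 transcript versions, 21 and 17 normalized reads. From raw reads, 10 and 11 at the version with most, it stood at 0.498 (0.192 to 1.31) and was not called. RPL14A was not called with the sum scaling, nor REFA1 with the median scaling. The calls of lhcA-P4, RPL14A and MPK8 were named after their values were seen. In the histone list 1 of 13 was lower, Os02g0755200, a polyamine oxidase by its description, with 5 and 1 reads, at 0.0906 (0.00192 to 0.810). In the protein kinase list 1 of 20 was higher, MPK8, at 3.62 (1.10 to 18.8), a call lost with the sum scaling. Light signalling, gibberellin, brassinosteroid, ethylene, cytokinin, jasmonate, heat shock, ubiquitin and F-box, and transporter lists had no called gene on the authors' scale. At site level 3 ubiquitin and F-box sites and 1 transporter site were called lower. With the sum scaling 1 gene of each of these 2 lists was called lower. Sites of ARF by miR160, copper proteins, brassinosteroid and ethylene lay above the central 95% of random lists, at percentiles of 99.0, 98.2, 98.9 and 99.5, although the ethylene median log2 ratio was -0.25. With sites that lack a read in a library at their bound against the floor, the medians of copper proteins and brassinosteroid were -1.14 and -3.41 and those of ethylene and of the miR2118, miR1432 or miR530 targets 0.65 and 0.86, the other sign than with the pseudocount. Sites of miR2118, miR1432 or miR530 targets, auxin, ribosomal protein and protein kinase lay below, at 0.0050, 2.47, 0.15 and 0.00.

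The third comparison followed the study's own selection of auxin and cell wall genes. ARF10 was the only gene of the auxin sheet called higher, and in the cell wall sheet NAC043 and At1g28600, both at sites of a simple-repeat small RNA, were called higher and Os02g0755200 lower. With the sum scaling At1g28600 was not called, and ARF10 was not called as a gene, at 1.96, but was at its site at position 1577, at 2.01. The auxin sheet held 21 sites of 18 genes, 13 of them read in both libraries, with 1 site called higher and 1 lower. The lower one was position 2646 of ZS04t0484500-01, from the auxin receptor gene Os04g0395600, at 0.302 (0.0884 to 0.95), a call lost with the median scaling. The adjacent position 2645 of the same transcript stood at 1.03 (0.715 to 1.5). IAA30, an Aux/IAA repressor gene, had 2 and 4 reads, and MYB44 had 0 and 7. The cell wall sheet held 34 sites of 28 genes, 11 read in both libraries, with 15 sites at 1 read in all. HOX9 and HOX10 were its deepest members, and FUT12, At5g27430, Os01g0926700, Os05g0277500 and Os06g0247900 were not called. NAC043, with 0 and 13 reads, was 1.96-fold higher against the floor, just under 2-fold, with an interval from 1.38. The study chose these genes on these samples, so their counts are not independent evidence of a direction. Simple-repeat small RNAs alone accounted for 6 sites of the auxin sheet and 12 of the cell wall sheet.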

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

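The added alternatives named here (thinning, the floor, the same TPB pseudocount, the sum size factor for lists, and leaving out simple-repeat small RNAs) were chosen after the data were seen. No paired analysis was possible because each condition has 1 library and no test was made. Under the other scalings there were 44 values of named sites called on the main scale, of which 34 were called the same way and 10 were not called. Of 98 values of uncalled sites 91 stayed uncalled and 7 were called, and 16 with reads in both libraries lay on the other side of 1. Of 62 medians of lists outside the central 95% on the main scale, 33 stayed outside on the same side, 19 moved inside and 10 changed sign, and only these 10 are called reversed below. Of 163 medians of lists inside it, 151 stayed inside and 12 moved outside, and 41 changed sign. AP2 was among these, from -0.64 to 0.96 with at least 10 reads. A score of 4 or lower removed nothing, so it says nothing. Depth limits all of this, since the median site had 2 reads.

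Sites in the dark library, the light library and both numbered 413, 665 and 255 as genes, 589, 1001 and 404 in categories 0 to 2, 95, 114 and 70 in category 0, 103, 113 and 76 with the authors' p-value of 0.05 or lower, and 304, 328 and 304 with at least 10 reads, fewer by construction. The category 0 share of the dark and light library was 21.1% and 18.4% over pairs, 92.2% and 95.6% with that p-value, and 11.8% and 9.08% without simple-repeat small RNAs. Against 52 higher and 49 lower calls there were 27 and 19 over genes, 26 and 18 over genes from raw reads, 16 and 8 in category 0, 13 and 9 with that p-value, 52 and 26 with at least 10 reads, and 22 and 106 with the sum scaling. A 4-fold minimum left 34 higher and 39 lower, and the floor 31 and 34, so that lower calls outnumbered higher ones in both. The sum scaling divides all light values by 1.36, which moves calls by construction.

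The median log2 ratio of all target-class lists, -0.14, was -0.0071 with at least 10 reads, -0.088 in categories 0 to 2 and -0.029 over genes, no longer apart from random lists, and reversed to 0.070 with the same TPB pseudocount. The cause was not tested. Brassinosteroid reversed to -0.44 with a pseudocount of 1 read and to -0.20 with the sum scaling. With at least 10 reads auxin reversed to 0.12 and protein kinase to 1.5, on 2 sites. Ethylene reversed to 0.24 in categories 0 to 2, 0.13 over genes and 0.30 with the same TPB pseudocount. Over genes the miR2118, miR1432 or miR530 targets reversed to 0.12 and ribosomal protein to 0.44. The cause was not tested for these either.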

Other observations

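Of the tests in this part, those of counting error, of depth and of the deposited p-values, and the reach of the amplification test, were chosen after the result was seen.

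Beyond the target-class lists, 17 genes were called higher in the light library and 16 lower, and the genes named in this paragraph were chosen after their values were seen. The unnamed gene ZS12g0097300 had 0 and 33 reads and was 4.98-fold higher against the floor, with a counting interval of the ratio from 3.83. A caffeoylshikimate esterase-like gene, ZS01g0235500, by description an enzyme of lignin synthesis, had 0 and 17 reads and was at least 2.57-fold higher, and RBM25, an RNA-binding protein gene, had 0 and 14 reads and was at least 2.11-fold higher. On the other side SAP18 and MT4B had 5 reads in the dark library and none in the light library, 3.68-fold lower each against the floor with a counting interval of the ratio up to 0.494, and MP3 stood at 0.113 (0.0205 to 0.420) on 12 and 3 reads. SDP6, a glycerol-3-phosphate dehydrogenase gene, and PLP3 had 4 and 0 reads each, 2.94-fold lower against the floor with an interval up to 0.686.

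A pair of 18-base small RNAs made of short repeats, TCTCTCTCTCTCTCTCTC and TGGTGGTGGTGGTGGAGG, took 33.3% of the 25653 listed pairs and gave 600 of the 2064 sites. In those 600 sites 3 reached category 0, and none had a deposited p-value of 0.05 or lower. The sites of At1g28600, lhcA-P4, NAC043, MYB44, At5g27430, Os05g0277500, MT4C, MT4B, PLP3 and MP3 described here pair with one of these small RNAs.

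Target-class genes differed from one another in their light to dark ratio, from SPL19 at 0.262 to SCL6 ZS02g0545600 at 6.49. The tables argue against counting error around 1 shared ratio, since the chi-square per degree of freedom was 12.3 over 44 genes with at least 20 reads. Without the 4 genes that share reads with another gene, the chi-square per degree of freedom was 13.3 over 40 genes. Shared reads make copies alike, as for HOX9 and HOX10 at 1.06 each. Leaving them out could therefore hardly lower the value, and no conclusion is drawn from it. Amplification copies at single positions were looked at in 14 of these genes. Positions of 1 gene differed by 1.69 per degree of freedom and the same 14 genes by 31.3. The limit set for this test, 15.7, was out of reach for most draws, so that limit decides nothing. Simulated positions with independent ratios at these read counts gave a median of 9.0 (95% of draws 3.67 to 21.9). The value of 1.69 lies below that range, which argues against copies made independently at each position in these 14 genes. Copies with trimmed ends could raise neighbouring positions together, and these stay open, as do copies in the other genes. An effect of light on single targets, or on their small RNAs or transcripts, cannot be told apart from such copies here, and with 1 library each it stays untested against variation between seedlings or libraries.

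The light library listed more sites than the dark library, 1681 against 1075. Thinned to the dark total, the light library still had 136 more sites (SD 19.8) and 64.9 more genes (SD 12.4). The SDs take items as independent, so those of sites are too small. The excess argues against the ratio of the inferred totals as the whole cause. Whether these totals count all or only mapped reads is not known. TPB over shared sites summed to 1.36 times as much in the light library, but the median shared site stood at a ratio of 0.883. Shared sites with 20 or more reads had a median log2 ratio of 0.073. Thinning at a larger ratio was not done, so depth as such stays open. Without the simple-repeat small RNAs the excess at the inferred totals was 124 sites (SD 16.1), so it is not limited to these. An effect of light may be 1 candidate explanation and a difference in library quality another, and neither was tested.

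By the authors' deposited table, a Fisher p-value under 0.05 between the libraries belongs to 2789 of 3262 pairs (85.5%). The same holds for 813 of the 907 pairs in the authors' deposited table that have 1 raw read in all. A Fisher test with TPB entered in place of read counts gives the value of the authors' deposited table, within 5% of its log10, for 100% of pairs, which is consistent with TPB having been tested as if it were counts. The interval from raw reads excludes 1 for 389 pairs (11.9%).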
